A study of Mus musculus with 24 samples.

How the data were processed

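Mouse RNA was measured in 24 libraries of 6 groups, which the sample labels name. Per the labels' protocols, 1000 cells per well were sorted and lysed, the cytoplasmic RNA was separated, mRNA was reverse transcribed from an oligo-dT primer and the product was amplified before sequencing. Per the submitters' processing notes, CASAVA 1.8.2, TopHat2 2.0.4, HTSeq and the mouse build mm9 were used by the authors. The role and settings of each tool, the gene annotation and the strand setting are not given in the sources used here. The authors deposited raw read counts per gene symbol for every library, whole numbers that had not been normalized, for 23283 genes, of which 1708 had no count in any library. Reads of a gene and its antisense or overlapping partner, and of near-identical copies such as keratin genes, cannot be told apart from such counts. No row lacked a gene name.

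Library totals ran from 2098846 to 18648132 counts. A floor of 3 counts over a group stands for a gene with no count there, and lower bounds of folds were computed against it. These bounds cover counting error only, because reads amplified by PCR are not independent molecules. None of 37 pairs of libraries within a group were identical, and the lowest chi-square per degree of freedom of a pair was 48.7, so every library was counted as its own sample.

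Groups were compared with edgeR 4.0.16 (quasi-likelihood F test, robust fit, TMM factors, filterByExpr) in R 4.3.3, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05, two-sided. Only the groups compared entered each fit, without a block. The comparisons were fast against slow MEF, iPS against bulk MEF, slow and fast MEF each against bulk MEF, fast against slow GMP, and the interaction of gate and cell type. Standard errors of log2 fold changes came from the same fits. CPM values beside a fold change used the TMM factors of that comparison. Values of Nanog, keratin 14, list sums and the plots used factors over all 24 libraries.

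The design, the alternatives and 34 gene lists with 644 members were fixed before the data were examined, from textbook knowledge. Of the members, 618 matched a symbol in the file, 8 a synonym and 18 neither, and none of the mitochondrially encoded genes matched. The keratinocyte list was added after the data were seen. A list was described by how many members passed, over all genes and adjusted over the list alone, and tested with camera of limma 3.58.1 at an inter-gene correlation of 0.01 and again with an estimated correlation. Lists with under 3 tested members had no camera test.

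Genes were named by a rule. It took Pou5f1, Sox2, Klf4, Myc, Nanog, Trp53, Cdkn1a and Cdkn1c wherever tested. It took the 8 highest and 8 lowest fold changes per comparison among genes past the threshold with non-overlapping libraries and at least 20 CPM in the higher group (for the interaction, the 8 smallest p of each sign). It took up to 4 members of each described list in the leading direction and up to 2 in the other. Any other gene is said to have been chosen after its values were seen. Some genes that the rule names are not reported here.

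The axis was a projection of log2 CPM (prior count 2) on the line from the bulk MEF mean to the iPS mean, over 5315 genes called between these groups with at least a 2-fold change. Fast and slow libraries were compared on it by exact permutation with scipy 1.17.1. Tables and plots were made with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

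The tests were tried on simulated counts with the means, spread and depth of each comparison. For fast against slow MEF, 13 of 48 genes changed by 4-fold and 42 of 49 changed by 16-fold were called in the right direction, with 4 false calls among 106 over 11539 genes. For iPS against bulk MEF these were 3 of 49 and 46 of 49 over 11553 genes. For the interaction, 0 of 50 and 6 of 50 were called over 13506 genes. Few genes were changed in each simulation, while 3726 genes passed in the real MEF comparison of gates and 5566 in iPS against bulk MEF. The adjustment is more lenient where many genes change, so these shares are not the power of those real comparisons.

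Alternatives were DESeq2 size factors or upper-quartile factors in edgeR, no filter or a stricter filter on low counts, DESeq2 1.42.0, limma voom with sample quality weights, the replicate number as a block, all 24 libraries in 1 fit, counts thinned to the smallest library, and each library left out in turn. A fit without Rn45s and Lars2 was added after the data were seen.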

Results

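RNA was measured in 24 mouse libraries from 6 cell populations, each made from the cytosolic RNA of 1000 cells sorted into a well. Mouse embryonic fibroblasts (MEF) gave 4 untreated bulk libraries. Another 8 came from MEF in which doxycycline had induced the Yamanaka factors (Oct4, encoded by Pou5f1, with Sox2, Klf4 and Myc) for 6 days. Those cells were sorted after 48 hours of dilution of CFSE, a dye that each division dilutes, into 4 fast and 4 slow cycling libraries. Granulocyte monocyte progenitors (GMP), the committed blood progenitors of neutrophils and monocytes, gave 5 fast and 3 slow cycling libraries after 24 hours of CFSE dilution. The last 4 libraries were factor-independent induced pluripotent stem cells (iPS) sorted for an Oct4 reporter. The labels call iPS fast and bulk MEF slow cycling, and bulk MEF unsorted, although the protocol given for all libraries has cells sorted into wells.

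Total counts ran from 2098846 to 18648132 per library. The 8 GMP libraries held 2098846 to 4411526 counts and the other 16 held 4937453 to 18648132. Rn45s and Lars2, annotated genes that collect ribosomal RNA reads, together took 19.9% to 48.86% of the counts of each GMP library and 3.05% to 11.73% elsewhere. The median correlation of a library with its own group was 0.67 to 0.787 in GMP and 0.916 to 0.97 in the other groups. Fast GMP replicate 1 had counts in 18402 genes, against 9380 to 14168 in the other GMP libraries. The labels do not say that replicates came from separate animals or cultures, so p-values measure the spread between these libraries, which may be technical.

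**Figure D1:**
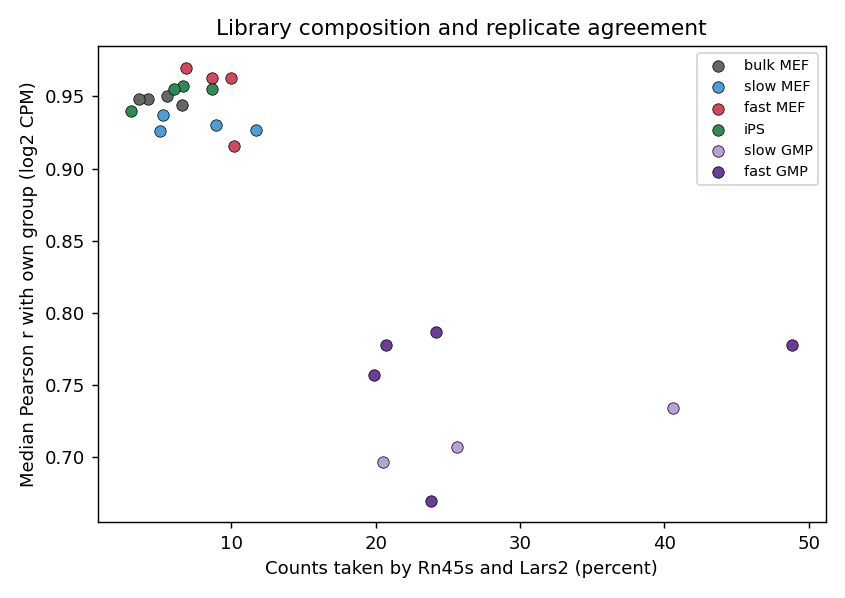
Each point is 1 of the 24 libraries, with the percent of its counts taken by Rn45s and Lars2 on the x axis and its median correlation with the other libraries of its group (Pearson r of log2 CPM) on the y axis. The 8 GMP libraries lie at 19.9% or more and at 0.787 or less, and the other 16 at 11.73% or less and 0.916 or more.

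Fast and slow cycling MEF, both from the induced culture, were compared to find which genes differ between the gates after 6 days of induction. All 4 factor genes rose in fast MEF. Sox2 stood at 338 ± 129 CPM in fast and 10.4 ± 7.11 CPM in slow MEF (SD, n = 4 each; log2 fold change 5.02 ± 0.54 SE, edgeR adjusted p = 0.000135). Pou5f1 rose by 4.65 ± 0.72, Myc by 3.54 ± 0.26 and Klf4 by 2.74 ± 0.43 on the log2 scale. Counts per gene do not tell the induced transgenes from the endogenous genes. The gates thus differed in factor mRNA as well as in dye dilution, and genes that go with either cannot be told apart here. In all, 3726 of 11742 genes passed the threshold, 1691 higher and 2035 lower in fast MEF. Far fewer passed with all 24 libraries in 1 fit, with the count given below under the processing.

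Proliferation genes rose together in fast MEF. Of 30 genes of G2 and mitosis, 27 rose and none fell (28 and 0 adjusted over the list alone, camera adjusted p = 1.96e-13). Among them were Cdc20 (3.18 ± 0.38), Mki67 (2.71 ± 0.35) and Top2a, the topoisomerase that separates replicated DNA (2.18 ± 0.25). Of 34 S phase genes, 22 rose and none fell (23 and 1 adjusted over the list alone, camera adjusted p = 8.01e-10). They were led by the replicative helicase subunit Mcm5 (3.81 ± 0.36), Lig1 (3.46 ± 0.40) and Pcna (2.48 ± 0.26). Of 27 genes of the nucleolus and ribosome biogenesis, 22 rose and none fell (25 and 0 adjusted over the list alone, camera adjusted p = 9.92e-11), including Ddx21 (2.61 ± 0.29) and Fbl (2.21 ± 0.25). The cell cycle inhibitor and quiescence genes fell in 9 and rose in 3 of 16 (10 and 3 adjusted over the list alone, camera adjusted p = 0.0171, and adjusted p = 0.107 with an estimated correlation). Cdkn1c, an imprinted inhibitor of cyclin-dependent kinases, fell from 63.1 ± 33.9 to 1.47 ± 0.86 CPM (log2 -5.36 ± 0.64), Gas1 fell (-4.50 ± 0.43) and Cdkn1a, the p53 target p21, fell less (-0.98 ± 0.22). The list also holds D-type cyclin genes, which are not inhibitors, so its counts are not those of inhibitors alone. Of these, Ccnd1 rose (2.62 ± 0.30) while Ccnd2 fell (-2.25 ± 0.20). Of 25 p53 targets, 12 fell and 2 rose (12 and 2 adjusted over the list alone, camera adjusted p = 0.0353, and adjusted p = 0.0892 with an estimated correlation). Trp53 itself was at -0.29 ± 0.23 (adjusted p = 0.376).

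Fibroblast genes were lower and epithelial genes higher in fast MEF. Of 28 fibroblast extracellular matrix genes, 27 fell and none rose (28 and 0 adjusted over the list alone, camera adjusted p = 2.1e-19). Sparc, a collagen-binding matrix protein, fell from 47250 ± 4988 to 5724 ± 717 CPM (log2 -3.04 ± 0.15), Bgn (-4.41 ± 0.21) and Mmp2 (-4.79 ± 0.29) fell too. Of 18 mesenchymal transcription factor and Tgfb genes, 16 fell and 1 rose (17 and 1 adjusted over the list alone, camera adjusted p = 1.25e-07). Prrx1 was at -2.84 ± 0.25 and Foxd1, which rose, at 6.87 ± 1.13. Of 13 contractile genes, 11 fell (12 adjusted over the list alone, camera adjusted p = 7.25e-07), such as Acta2 (-4.23 ± 0.27) and Myl9 (-4.49 ± 0.34). Of 21 epithelial genes, 18 rose and 1 fell (18 and 1 adjusted over the list alone, camera adjusted p = 5.75e-10, and adjusted p = 0.0583 with an estimated correlation). Krt8 reached 1918 ± 272 CPM in fast MEF (5.88 ± 0.88), Cdh1, the adhesion molecule E-cadherin, rose by 6.06 ± 0.87 and Dsp, a desmosome protein, by 5.02 ± 0.59, and Cdh3, P-cadherin, fell (-3.86 ± 0.42). Fast MEF also carried keratin 14 at 9870 ± 2250 CPM, against 225 ± 225 in slow MEF and 2.79 ± 2.6 in bulk MEF; this gene was chosen after its values were seen.

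Secreted factors and interferon genes were lower in fast than in slow MEF. Of 15 secreted inflammatory and senescence genes, 14 fell and none rose (14 and 0 adjusted over the list alone, camera adjusted p = 4.64e-09), among them Igfbp3 (-4.63 ± 0.53) and Mmp13 (-4.93 ± 0.49). Of 18 interferon response genes, 12 fell and none rose (13 and 0 adjusted over the list alone, camera adjusted p = 1.1e-06, and adjusted p = 0.0529 with an estimated correlation), including Ifit3 (-5.14 ± 0.88). Of 19 imprinted genes, 10 fell and 1 rose (10 and 1 adjusted over the list alone, camera adjusted p = 0.00229, and adjusted p = 0.0641 with an estimated correlation); H19 fell from 3505 ± 753 to 201 ± 43.9 CPM (-4.13 ± 0.24). Of 18 genes of DNA methylation and Polycomb, 6 rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.00536, and adjusted p = 0.114 with an estimated correlation). Uhrf1 was at 4.08 ± 0.49 and Dnmt1 at 2.58 ± 0.31. Of 7 neural genes, 5 rose and 1 fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.0184, and adjusted p = 0.0878 with an estimated correlation). Stmn2, a neuronal tubulin regulator, reached 3621 ± 473 CPM (5.27 ± 0.73). Of 18 tested pluripotency genes, 7 rose and 1 fell (12 and 1 adjusted over the list alone, camera adjusted p = 0.000333, and adjusted p = 0.0583 with an estimated correlation). The rises include the induced factors Pou5f1, Sox2 and Klf4, whose transgene reads cannot be told from endogenous ones. L1td1 was at 6.02 ± 0.69 and Klf2, which fell, at -4.29 ± 0.99. Nanog was too low to test, at 1.43 ± 1.03 CPM in fast MEF and 36.8 ± 2.22 CPM in iPS.

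Among genes with non-overlapping libraries, the highest fold changes in fast MEF were those of Sh3tc1 (9.80 ± 1.96), Tlx2 (9.62 ± 0.80), Tnk1 (8.65 ± 1.05), Smagp (7.60 ± 0.88), Miat (7.29 ± 1.09), 2300002M23Rik (6.98 ± 1.41) and Bhlha15 (6.96 ± 1.24). Fast MEF replicate 3 alone set much of the size of some: it stood at 3462 CPM for Sh3tc1 and 172 for Bhlha15, against at most 52.0 and 22.3 CPM in the other fast MEF libraries. Without it they were at 5.46 and 5.34, and 2300002M23Rik was at 5.73 without fast MEF replicate 4. The lowest were Gng8 (-8.48 ± 1.30), Hlx (-8.24 ± 0.94), Hgf (-7.30 ± 1.32), Siglecg (-7.01 ± 1.24), Dnajb5 (-6.99 ± 1.28), Gzme (-6.93 ± 1.30), Zfp580 (-6.86 ± 1.01) and Dusp23 (-6.83 ± 0.83). Foxd1, Tlx2, Tnk1 and Miat had counts in slow MEF only in replicate 2. Gzme had counts in fast MEF only in replicate 1, and Siglecg only in replicate 3. Those counts held these folds down. Without that library Foxd1 was at 11.4, Tlx2 at 11.9, Tnk1 at 11.0, Miat at 12.0, Gzme at -11.0 and Siglecg at -10.5. All of them stayed past the threshold, and their size was then set against a group with no count. Leaving out 1 library made the fold of 29 of the 69 named genes past the threshold larger by over 1.5 times. Without slow MEF replicate 3 Gng8 was at -6.86, Hgf at -6.28 and Dnajb5 at -6.26. The Yamanaka factor and mast cell lists passed (camera adjusted p = 0.000352 and 0.0468) but not with an estimated correlation (adjusted p = 0.114 each). Of 3 mast cell genes, Il1rl1 (-4.10 ± 0.53) and Mcpt8 (-4.80 ± 1.17) fell, and Csf2rb2 was at 1.94 ± 1.8 (adjusted p = 0.449). Mcpt8 was at -4.17 without slow MEF replicate 2. The direction of Csf2rb2 rested on fast MEF replicate 3, at 32.9 CPM, and was -5.51 without that library. Glycolysis (6 rose and 3 fell of 20), oxidative phosphorylation (2 and 2 of 33), cholesterol synthesis (1 and 2 of 20) and immediate early genes (1 and 4 of 16) did not pass as lists (camera adjusted p = 0.569, 0.271, 0.315 and 0.483).

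**Figure D2:**
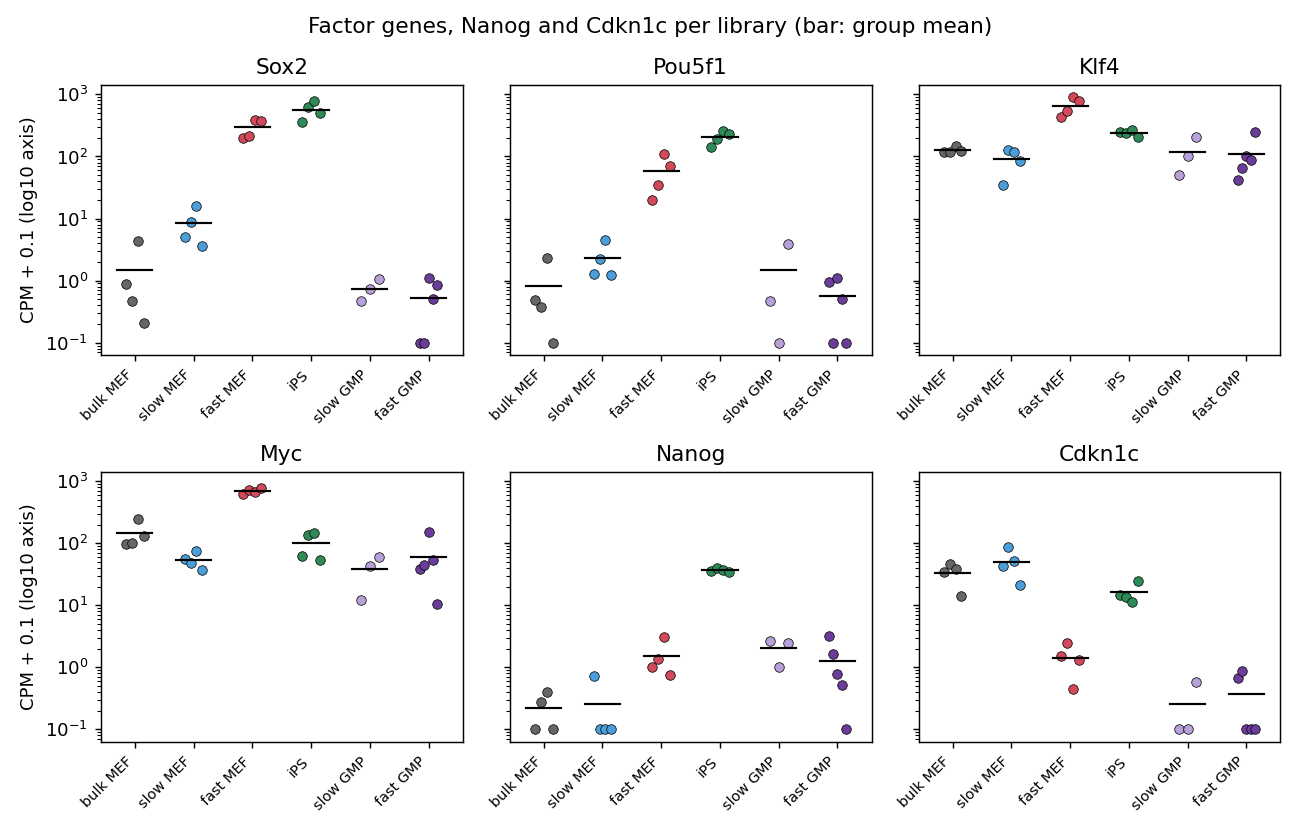
Each point is a library and each bar a group mean, for Sox2, Pou5f1, Klf4, Myc, Nanog and Cdkn1c, on a log10 axis of CPM with 0.1 added. Sox2 lies between 200 and 391 CPM in the fast MEF libraries and at 16.1 CPM or less in slow MEF.

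Bulk MEF and iPS mark the start and the end of reprogramming. The pluripotency list rose in all 33 of its tested genes in iPS (33 adjusted over the list alone, camera adjusted p = 1.34e-17, and adjusted p = 0.0967 with an estimated correlation). Sox2 stood at 614 ± 185 CPM against 1.56 ± 2.21 CPM in bulk MEF (log2 8.62 ± 0.96, n = 4 each, edgeR adjusted p = 8.84e-05). Pou5f1 rose by 8.08 ± 0.93, Nanog by 8.06 ± 0.80, Utf1 by 9.42 ± 0.52 and Dppa4 by 11.11 ± 0.72. Without bulk MEF replicate 3 Sox2 was at 10.30 and Pou5f1 at 9.71, and the fold of 22 of the 57 named genes past the threshold was larger by over 1.5 times without 1 library. In all, 5566 of 11736 genes passed, 2828 higher and 2738 lower in iPS. More were lower with all 24 libraries in 1 fit (1502 higher and 1668 lower), with thinned counts (2511 and 2640), without iPS replicate 1 (2563 and 2724) and without iPS replicate 3 (2374 and 2634).

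All 30 genes of G2 and mitosis rose in iPS (30 adjusted over the list alone, camera adjusted p = 3.6e-11), as did 29 of 34 S phase genes (30 adjusted over the list alone, camera adjusted p = 3.77e-10) and 23 of 27 nucleolar genes (27 adjusted over the list alone, camera adjusted p = 8.07e-07). Ube2c rose by 3.50 ± 0.28, Mcm7 by 3.29 ± 0.26 and Npm1 by 2.27 ± 0.31. Of 18 genes of DNA methylation and Polycomb, 14 rose and 1 fell (14 and 2 adjusted over the list alone, camera adjusted p = 2.72e-05, and adjusted p = 0.107 with an estimated correlation). Dnmt3b, a de novo DNA methyltransferase, was at 8.44 ± 0.91. All 27 extracellular matrix genes fell (27 adjusted over the list alone, camera adjusted p = 2.05e-15, and adjusted p = 0.0967 with an estimated correlation), among them Sparc (-4.34 ± 0.15) and Col6a1 (-8.09 ± 0.43), and so did 13 of 14 contractile genes (13 and, for higher, 1 adjusted over the list alone, camera adjusted p = 3.24e-08, and adjusted p = 0.0647 with an estimated correlation), such as Cnn1 (-8.01 ± 0.34). Of 17 mesenchymal genes, 15 fell (16 adjusted over the list alone, camera adjusted p = 4.89e-08, and adjusted p = 0.0624 with an estimated correlation). Of 19 epithelial genes, 14 rose and 2 fell (14 and 2 adjusted over the list alone, camera adjusted p = 2.72e-05, and adjusted p = 0.0725 with an estimated correlation). Epcam was at 9.16 ± 0.73 and Krt19, which fell, at -2.40 ± 0.88. Krt19 was at -1.49 (adjusted p = 0.177) without bulk MEF replicate 3 and also missed the threshold without bulk MEF replicate 2 or iPS replicate 1, 3 or 4. Cdkn1a fell from 4330 ± 835 to 190 ± 13.9 CPM (-4.51 ± 0.21), Trp53 rose (1.85 ± 0.20) and Klf4 rose (0.88 ± 0.22). Myc was at -0.58 ± 0.44 (adjusted p = 0.302) and Cdkn1c at -1.09 ± 0.45 (adjusted p = 0.0725), which passed without bulk MEF replicate 4 (-1.36, adjusted p = 0.0219) or iPS replicate 4 (-1.37, adjusted p = 0.048).

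Immediate early genes fell in 13 of 16 cases in iPS (13 adjusted over the list alone, camera adjusted p = 2.72e-05), including Egr1 (-4.72 ± 0.33) and Jun (-4.86 ± 0.50), and secreted factors in 9 of 10 (9 adjusted over the list alone, camera adjusted p = 1.45e-05), such as Igfbp5 (-8.20 ± 0.45). Of 7 endothelial genes, 5 rose (5 adjusted over the list alone, camera adjusted p = 0.0104, and adjusted p = 0.121 with an estimated correlation), with the adhesion molecule Pecam1 at 108 ± 10.5 CPM (6.83 ± 1.06). Of 20 imprinted genes, 12 fell and 3 rose (13 and 3 adjusted over the list alone, camera adjusted p = 0.0133, and adjusted p = 0.122 with an estimated correlation); Igf2 fell (-4.21 ± 0.25) and Peg10 rose (3.97 ± 0.53). Among the largest differences, Olig2, Rhox1, Aire, Phlda2, 2410007B07Rik, Mageb16 and Pacsin1 had no count in bulk MEF and were at least 765-, 476-, 264-, 268-, 253-, 280- and 273-fold higher in iPS, against a floor of 3 counts over the group. The bound of Rhox1 was 281-fold without iPS replicate 4. Foxs1 had no count in iPS and was at least 1040-fold lower. Ntn4 (-10.20 ± 0.88), Irf2 (-9.75 ± 1.60), Scarf2 (-9.73 ± 0.95), C1qc (-9.66 ± 0.61), Dok5 (-9.51 ± 0.81), Irx1 (-9.45 ± 0.77) and Aspn (-9.33 ± 0.70) followed. Irf2 was at -8.94 without bulk MEF replicate 1. The inhibitor list passed (camera adjusted p = 0.00314) but not with an estimated correlation (adjusted p = 0.0647).

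Slow cycling MEF differed from untreated bulk MEF in factor induction, medium, dye labelling and the dye gate at once. Sox2 and Pou5f1 mRNA did not differ past the threshold between slow and bulk MEF. Sox2 was at 9.02 ± 6.16 and 1.44 ± 2.01 CPM (log2 2.64 ± 1.0, n = 4 each, edgeR adjusted p = 0.122), Pou5f1 at 2.38 ± 1.67 and 0.754 ± 1.06 CPM (adjusted p = 0.368), and Myc fell (-1.38 ± 0.38, adjusted p = 0.0377). Sox2 passed without bulk MEF replicate 3 (4.29, adjusted p = 0.0263). Myc did not pass without bulk MEF replicate 3 (-1.0, adjusted p = 0.0948) or 4, or slow MEF replicate 1, 2 or 4. In all, 1181 of 11253 genes passed, 620 higher and 561 lower in slow MEF. The count was 762 without bulk MEF replicate 4, 759 without slow MEF replicate 3, 1976 with DESeq2 and 56 with all 24 libraries in 1 fit. With the replicate block 424 were higher and 446 lower. The fold of 12 of the 32 named genes past the threshold was larger by over 1.5 times without 1 library.

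Of 18 interferon response genes, 11 rose and none fell in slow MEF (14 and 1 adjusted over the list alone, camera adjusted p = 2.05e-11), including Usp18 (6.52 ± 1.16), Ifit1 (5.77 ± 1.09) and Ifit3 (4.59 ± 0.69). Of 14 contractile genes, 9 fell (13 adjusted over the list alone, camera adjusted p = 7.72e-11): Acta2, smooth muscle actin, fell from 8455 ± 1293 to 1873 ± 215 CPM (-2.17 ± 0.17), and Tagln (-2.46 ± 0.17) and Ctgf (-3.90 ± 0.30) fell. Of 20 cholesterol synthesis genes, 6 fell (9 adjusted over the list alone, camera adjusted p = 3.88e-06), such as Fdps (-2.58 ± 0.29). Of 27 nucleolar genes, 7 fell and 1 rose (10 and 1 adjusted over the list alone, camera adjusted p = 0.000285), with Ppan at -3.07 ± 0.62 and Npm1, which rose, at 0.91 ± 0.25. Npm1 did not pass without bulk MEF replicate 1, 3 or 4 or slow MEF replicate 1, 2 or 3 (adjusted p from 0.0632 to 0.11). Of 28 extracellular matrix genes, 12 rose and 2 fell (15 and 2 adjusted over the list alone, camera adjusted p = 0.00272, and adjusted p = 0.245 with an estimated correlation). Pdgfra was at 3.87 ± 0.53, Col3a1 at 2.88 ± 0.40 and Vim, which fell, at -1.35 ± 0.19. Of 15 secreted factors, 8 rose and 3 fell (10 and 3 adjusted over the list alone, camera adjusted p = 0.00272, and adjusted p = 0.098 with an estimated correlation): Mmp13 (6.03 ± 0.67) and Igfbp3 (5.47 ± 0.38) rose. Imprinted genes rose in 6 and fell in 1 of 20 (7 and 1 adjusted over the list alone, camera adjusted p = 0.0352, and adjusted p = 0.114 with an estimated correlation), led by H19 (2.95 ± 0.20), and oxidative phosphorylation genes fell in 6 of 33 (6 adjusted over the list alone, camera adjusted p = 0.00186, and adjusted p = 0.403 with an estimated correlation), such as Uqcrc1 (-2.33 ± 0.33).

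The S phase list fell in 2 of 32 genes (1 adjusted over the list alone, camera adjusted p = 0.0172, and adjusted p = 0.0949 with an estimated correlation) and none of 30 G2 and mitosis genes passed (0 adjusted over the list alone, camera adjusted p = 0.318). The largest rises were Pamr1, with no count in bulk MEF and at least 283-fold higher, Serpina3n (10.27 ± 0.67), Adh1 (9.0 ± 1.34), Islr (8.71 ± 1.06), Ifi203 (8.49 ± 1.05), A4galt (8.10 ± 1.13), Krt16 (7.53 ± 1.03) and Abi3bp (6.47 ± 1.10). Without slow MEF replicate 4 A4galt was at 6.20 and Krt16 at 6.48, without slow MEF replicate 1 Islr was at 8.05 and Ifi203 at 7.56, and without slow MEF replicate 2 Adh1 was at 7.68. The largest falls besides Ctgf were Lce1h (-8.29 ± 1.40), Acta1 (-5.50 ± 0.44), Mmp9 (-5.33 ± 0.64), Dusp4 (-4.91 ± 0.71), Nes (-4.11 ± 0.61), Nptx2 (-3.83 ± 0.51) and Mgll (-3.70 ± 0.54). Lce1h was at -7.61 without bulk MEF replicate 2. The mesenchymal, early progenitor and immediate early lists passed (camera adjusted p = 0.0134, 0.0121 and 0.0114) but not with an estimated correlation (adjusted p = 0.221, 0.103 and 0.0949). With upper-quartile factors the split was 679 higher and 489 lower.

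Fast cycling MEF differed from bulk MEF in the same conditions, with the fast gate. Sox2 rose from 1.6 ± 2.27 to 327 ± 127 CPM (log2 7.67 ± 0.93, n = 4 each, edgeR adjusted p = 0.000162), Pou5f1 by 6.29 ± 1.06, Klf4 by 2.31 ± 0.29 and Myc by 2.18 ± 0.32. Cdkn1c fell (-4.71 ± 0.62), as did Cdkn1a (-1.19 ± 0.21) and Trp53 (-0.71 ± 0.20, and adjusted p = 0.07 without fast MEF replicate 2). Sox2 was at 9.35 and Pou5f1 at 7.92 without bulk MEF replicate 3, and the fold of 13 of the 33 named genes past the threshold was larger by over 1.5 times without 1 library. In all, 3958 of 11335 genes passed, 1869 higher and 2089 lower in fast MEF. More were higher with DESeq2 size factors (2010 higher and 1964 lower), upper-quartile factors (2078 and 1890) and all 24 libraries in 1 fit (822 and 691).

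Of 21 epithelial genes, 18 rose and 1 fell in fast against bulk MEF (18 and 1 adjusted over the list alone, camera adjusted p = 3.13e-11). Krt8 was at 11.45 ± 0.57, Crb3, an apical polarity protein, at 11.00 ± 0.66 and Epcam at 8.61 ± 0.79. All 14 contractile genes fell (14 adjusted over the list alone, camera adjusted p = 3.13e-11), with Acta2 at -6.37 ± 0.28 and Myl9 at -6.39 ± 0.34. Of 28 extracellular matrix genes, 25 fell (25 adjusted over the list alone, camera adjusted p = 2.84e-13, and adjusted p = 0.0769 with an estimated correlation), with Vim at -4.28 ± 0.23. G2 and mitosis genes rose in 26 of 30 (28 adjusted over the list alone, camera adjusted p = 3.13e-11), S phase genes in 23 of 34 (23 and, for lower, 1 adjusted over the list alone, camera adjusted p = 1.41e-07) and nucleolar genes in 14 of 27 (14 adjusted over the list alone, camera adjusted p = 0.000197). Of 24 p53 targets, 11 fell and 1 rose (11 and 2 adjusted over the list alone, camera adjusted p = 0.00598, and adjusted p = 0.19 with an estimated correlation): Mdm2 fell (-2.05 ± 0.31) and Perp, also a desmosome component, rose (6.32 ± 0.83). Of 20 pluripotency genes, 10 rose and 2 fell (12 and 2 adjusted over the list alone, camera adjusted p = 0.000143, and adjusted p = 0.203 with an estimated correlation), and 12 of 18 methylation and Polycomb genes rose (12 adjusted over the list alone, camera adjusted p = 0.000143, and adjusted p = 0.19 with an estimated correlation), such as Tet2 (4.57 ± 0.42). The pluripotency rises again include the induced factors Pou5f1, Sox2 and Klf4. Of 10 interferon genes, 1 rose, Xaf1 (3.39 ± 0.98; 0 adjusted over the list alone, camera adjusted p = 0.605), which missed the threshold without bulk MEF replicate 2 (adjusted p = 0.0512) or fast MEF replicate 2 (adjusted p = 0.0525).

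Pou4f2, Alox12b, Osbp2, Kiss1r, Dsc2, Tlx2 and Phlda2 had no count in bulk MEF and were at least 1950-, 945-, 741-, 772-, 787-, 614- and 513-fold higher in fast MEF, and Nova2 rose by 12.00 ± 0.61. Mmp9 and Slc16a11 had no count in fast MEF and were at least 1000- and 248-fold lower. The bound of Slc16a11 rested on bulk MEF replicate 4, at 72.2 CPM against 2.12 to 6.64 in the others, and was 53.8-fold without it. Siglecg (-9.76 ± 0.98), Hlx (-9.59 ± 0.85), 6230427J02Rik (-9.34 ± 0.92), Fjx1 (-8.20 ± 1.01), Gng8 (-8.06 ± 1.30, and -7.19 without bulk MEF replicate 1) and Ankrd1 (-7.85 ± 0.90) followed. The inhibitor, Yamanaka factor, mesenchymal, secreted factor, cholesterol and immediate early lists passed (camera adjusted p = 0.045, 0.00153, 0.00029, 0.000526, 0.0247 and 0.0442) but not with an estimated correlation (adjusted p = 0.168, 0.19, 0.136, 0.0946, 0.277 and 0.19).

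Fast and slow cycling GMP were compared to ask whether the dye gates carried the same genes in blood progenitors. The dye was diluted for 24 hours in GMP and 48 hours in MEF, so the gates need not differ equally in cycling speed. Both gates expressed Mpo, the neutrophil granule enzyme myeloperoxidase, at 10060 ± 6154 CPM in fast (n = 5) and 7379 ± 2800 CPM in slow GMP (n = 3). Mpo was chosen after its values were seen. Its fold change, 0.45, was -0.38 with the replicate block. The 11 primary granule genes summed to 20700 ± 10640 CPM in fast and 18810 ± 8403 CPM in slow GMP. In bulk MEF this sum was 6268 ± 1344 CPM while Mpo was at 0.862 ± 0.115 CPM (factors over all 24 libraries), so other members made up the sum there. Only 2 of the 11 genes had enough counts to be tested in fast against slow MEF. The sum is thus no measure of granule gene expression in MEF, and in GMP it may also hold genes that are not specific to granules. The 30 G2 and mitosis genes summed to 1503 ± 298 CPM in fast and 1574 ± 223 CPM in slow GMP. In MEF they summed to 2136 ± 322 CPM in the fast and 337.5 ± 59.8 CPM in the slow gate. The GMP gates thus did not differ in this sum as the MEF gates did. None of 10057 genes passed the edgeR threshold. At an unadjusted p under 0.05 there were 742 genes, where chance gives 503, and the smallest adjusted p was 0.662. DESeq2 called 97 genes, limma voom 0 and the fit of all 24 libraries, which takes 1 spread per gene over all groups, 385.

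In fast against slow GMP, none of the 34 S phase, 30 G2 and mitosis or 27 nucleolar genes passed (0 adjusted over the list alone), with median log2 fold changes of 0.11, 0.01 and 0.01. Myc was at 0.65 ± 1.0, Cdkn1a at 0.32 ± 0.94, Klf4 at -0.08 ± 0.87 and Trp53 at -0.90 ± 0.75. The direction of Cdkn1a rested on fast GMP replicate 4, at 3932 CPM against 286 to 816 in the other fast GMP libraries, and was -1.02 without it. Myc was at -0.02 without fast GMP replicate 3 and Klf4 at 0.55 without slow GMP replicate 3. The smallest list p was that of glycolysis (camera adjusted p = 0.133), with 17 of 19 genes above 0 and a median of 0.95. Adjusted over the list alone, 1 of 16 neutrophil maturation genes was higher, S100a9 (5.68 ± 1.37), 1 of 11 early progenitor genes lower, Meis1 (-5.26 ± 1.46), and 1 of 3 erythroid and megakaryocyte genes higher, Itga2b (8.17 ± 2.55). Each had an adjusted p of 0.662 over all genes. In simulated GMP libraries with this spread, 0 of 48 genes changed by 4-fold, 2 of 47 changed by 16-fold and 35 of 47 changed by 256-fold were recovered. Most differences of up to 16-fold would thus be missed if, as simulated, few genes changed.

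The test of the difference between the fast-slow effect in GMP and in MEF passed 193 of 13814 genes, 110 higher and 83 lower. The count was 1563 with DESeq2, 1069 with all 24 libraries in 1 fit, 324 with the stricter filter and 92 with the replicate block. More genes were lower than higher with limma voom (111 higher and 140 lower) and without fast GMP replicate 1 (255 and 320) or slow GMP replicate 1 (49 and 66), 2 (68 and 88) or 3 (61 and 109). Among the named genes, higher values, where the effect in GMP lay above that in MEF, were those of S1pr3 (7.64 ± 1.14), Fn1 (7.62 ± 1.23), Col12a1 (7.32 ± 1.14), Thy1 (7.02 ± 1.14), Nid1 (6.42 ± 0.99), Igfbp4 (5.90 ± 0.88), Col1a2 (4.80 ± 0.78) and Bgn (4.27 ± 0.64). Lower values were those of Tppp3 (-12.12 ± 1.85), Crb3 (-12.00 ± 2.00), L1td1 (-10.20 ± 1.44), Ccnb1ip1 (-9.38 ± 1.60), Srgn (-8.31 ± 1.11), Nup210 (-8.20 ± 1.23), Itga6 (-8.12 ± 1.21), Stmn2 (-5.69 ± 0.96) and Sox2 (-5.62 ± 1.30). With 1 library left out, Fn1 was at 6.15 and Igfbp4 at 5.26 (fast GMP replicate 5), Thy1 at 6.29 (fast GMP replicate 2) and Nid1 at 5.42 (fast GMP replicate 1). Nup210 was at -5.92 without slow GMP replicate 1, and Itga6 was at -6.47 and Crb3 at -11.0 without slow GMP replicate 3. Sox2 missed the threshold without any 1 of the slow GMP or MEF libraries except slow MEF replicate 3, with adjusted p from 0.0504 to 0.077. With factors over all 24 libraries, Sox2 was near 0 in GMP (0.432 ± 0.448 CPM in fast and 0.643 ± 0.291 CPM in slow). Its interaction value thus came mostly from MEF. The value of 8 of the 17 named genes past the threshold was larger by over 1.5 times without 1 library. Of 28 extracellular matrix genes, 13 were higher (21 adjusted over the list alone, camera adjusted p = 1.48e-20). Of 30 G2 and mitosis genes 1 was lower (11 adjusted over the list alone, camera adjusted p = 1.47e-11), of 34 S phase genes 2 (11 adjusted over the list alone, camera adjusted p = 4.68e-09) and of 23 epithelial genes 2 (12 adjusted over the list alone, camera adjusted p = 1.5e-13). These 4 list calls held with an estimated correlation between genes, with adjusted p from 0.00328 to 0.0128. The count of genes was 575 without fast GMP replicate 1, 115 without slow GMP replicate 1 and 82 to 101 when any 1 of the 8 MEF libraries was left out. With the MEF labels kept, 41 of the 56 groupings of the GMP libraries, the real one included, gave at least 193 genes, so a count of this size did not need the real GMP groups. Every such grouping keeps the MEF difference.

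The 3 fast against slow comparisons, counting iPS against bulk MEF, shared no gene past the threshold in the same direction among 8567 genes tested in all 3, since none passed in GMP. DESeq2 gave 5 shared genes and the fit of all 24 libraries 12. Fast against slow MEF and iPS against bulk MEF, which share no library, overlapped more than independent lists would. Both called 787 genes higher, where independent lists give 312.9 (Fisher odds ratio 5.92), and 1204 lower, where independent lists give 471.4 (8.73). The fit of all 24 libraries shared far fewer, as given below under the processing. The shared rises with the largest smaller fold, chosen after their values were seen, included Gpa33, Crb3, Zbtb32, N4bp3, Mtap7d2, Dok2, AU018091, Jag2, Lsr and Mtap7, and the shared falls Siglecg, Gzme, Hlx, Gng8, Maf, Grem1, Dusp23, Ltbp3 and Col11a1. Of these, in iPS, Dusp23 was at -5.90 and without bulk MEF replicate 2 at -2.45, and Crb3 at 6.87 and without iPS replicate 4 at 5.11. Across 10771 genes the fold changes of these comparisons correlated with r = 0.541 (rho 0.499), and without the cell cycle lists with r = 0.537. The GMP fold changes correlated with those of MEF at r = 0.009 and of iPS at 0.005. These are correlations across genes, which are not independent replicates.

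On an axis set to 0 at the bulk MEF mean and 1 at the iPS mean, slow MEF lay at 0.089 ± 0.011 and fast MEF at 0.454 ± 0.015 (SD, n = 4 each). All 4 fast libraries lay above all 4 slow ones, a difference of 0.365 (two-sided exact permutation p = 0.0286, the smallest that 4 against 4 allow). Slow GMP lay at 0.549 ± 0.006 (n = 3) and fast GMP at 0.546 ± 0.016 (n = 5; exact permutation p = 0.8571). GMP thus lay further along than fast MEF, although Pou5f1 was at 0.457 ± 0.471 CPM in fast and 1.38 ± 2.08 CPM in slow GMP. In iPS it was at 204 ± 51 CPM (factors over all 24 libraries). Of the 5315 axis genes, 2631 were lower in iPS than in bulk MEF, so low levels of bulk MEF genes also move a library up. A position is thus not by itself nearness to iPS or progress in reprogramming.

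**Figure D3:**
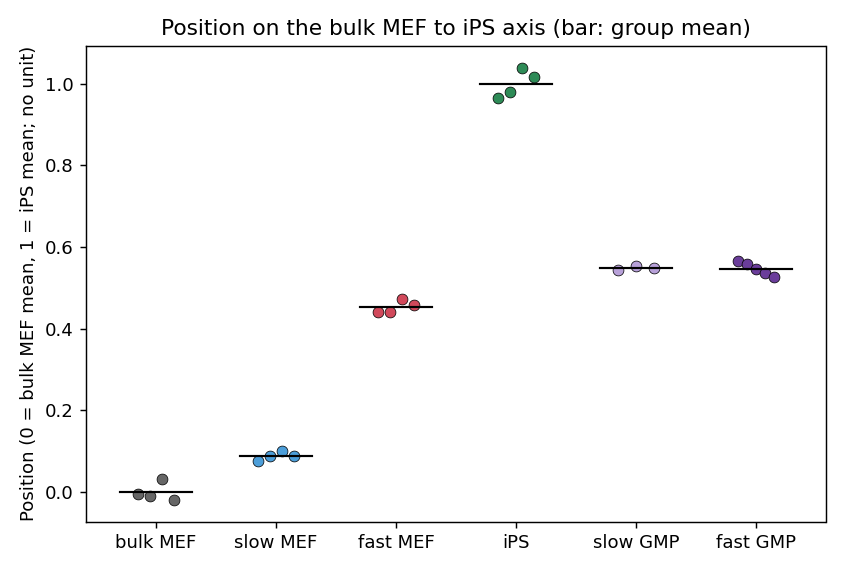
Each point is a library and each bar the group mean, with the position on the axis from the bulk MEF mean (0) to the iPS mean (1) on the y axis, which has no unit. The 4 fast MEF libraries lie between 0.442 and 0.474 and the 4 slow MEF libraries between 0.076 and 0.102.

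**Figure D4:**
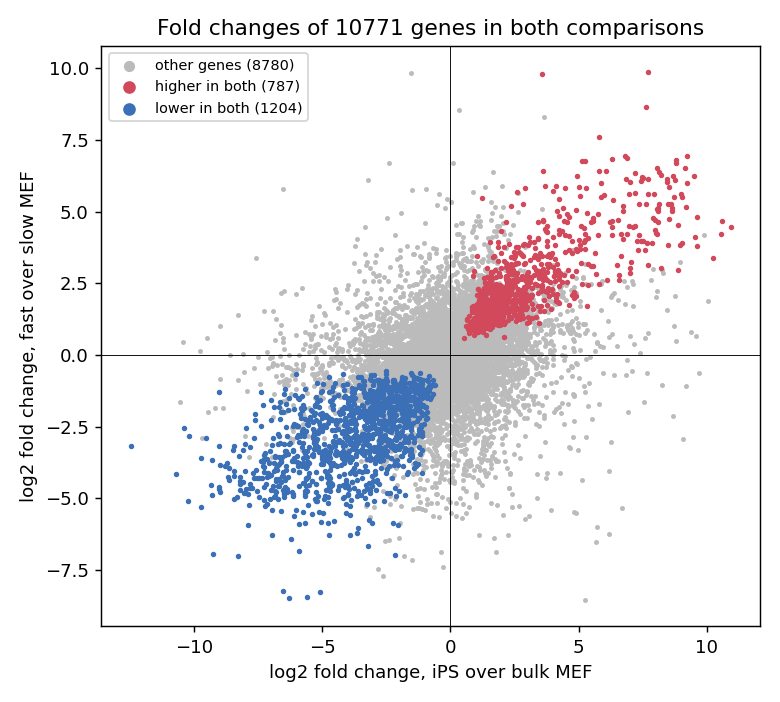
Each point is 1 of 10771 genes, with the log2 fold change of iPS over bulk MEF on the x axis and of fast over slow MEF on the y axis. The 787 genes higher in both are red, the 1204 lower in both blue, and the correlation across all points is 0.541.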

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

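The tests of exchanged labels, of a share of fast-gate cells, of keratinocytes and of shared keratin reads were chosen after the result was seen. The other tests were chosen before, except the groupings of GMP libraries with the MEF labels kept, for which no earlier plan was recorded.

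In slow MEF the mRNA of the induced factors was low, and the libraries did not overlap with fast MEF. Of the slow MEF libraries, 0 reached the lowest fast MEF library for the sum of the G2 and mitosis genes (396.4 against 1882 CPM), which argues against a swap of single libraries. Of 30 genes of G2 and mitosis, 27 were higher and 0 lower in the libraries named fast, which argues against an exchange of the whole groups. If slow MEF held some fast-gate cells, genes under 1 CPM in bulk MEF and over 100 CPM in fast MEF should imply a single share. Over 42 such genes the share had a median of 2.06% (0.105% to 9.62%) and 66.7% of them lay within a factor of 2 of it, so a small admixture and weak expression in slow cells cannot be told apart for these genes, whose shares are neither tight nor scattered. A biological difference between the gates, which the design names, stays open and was not tested.

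Keratin genes stood high in fast MEF. Krt5, abundant in keratinocytes beside Krt14, lay at 0.006% of Krt14, which argues against keratinocytes that express Krt5 in the sort. Of 24 keratinocyte genes, 5 were under 1 CPM while 11 were over 100 CPM, and 15 of 18 tested ones rose. The list as a whole thus does not settle whether keratinocyte-like cells were present. Of these 24 genes, other lists also hold Perp and Krt5. Of 17 tested epithelial genes that are not keratins, 14 rose, which argues against reads shared between keratin copies as the whole cause, while the copy each read belongs to stays open. A hypothesis is that part of an epithelial program may go with the fast gate.

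Between fast and slow GMP no gene passed with edgeR, with 742 at an unadjusted p under 0.05, 97 with DESeq2 and 0 with limma voom. MEF libraries thinned to the GMP totals still gave 3471 genes, which argues against read depth alone. Without fast GMP replicate 1 the count stayed at 0, which argues against that library alone. Among genes of at least 50 CPM in their group, 2.09% of GMP values were 0 against 0.0734% in the thinned MEF, so loss of transcripts before sequencing may add to the spread. In simulated GMP libraries with few genes changed, 0 of 48 genes changed by 4-fold and 2 of 47 changed by 16-fold were recovered. A lack of difference and differences of that size hidden by the spread were thus not separated.

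Other splits of the samples were counted for each comparison. All 56 splits of the GMP libraries gave at least 0 genes, the real value, and the highest of the others was 0. Of 35 splits each, only the real one gave as many genes in fast against slow MEF (3726) and iPS against bulk MEF (5566). The same held for slow against bulk MEF (1181) and fast against bulk MEF (3958). The highest of the others was 0 in each. Only 1 of 35 is the smallest share these splits allow, so chance is unlikely there but not excluded. The other splits mix the groups, so a group difference adds to their spread and lowers their counts. For the interaction, 3 of 100 drawn splits gave at least the real 193, the highest other 1209. The other splits that did so, with 1209 and 824 genes, kept or mirrored the MEF labels and so held the MEF difference, which is a structure of the samples. The splits that mixed the MEF labels gave at most 1 gene. The MEF labels thus fixed the outcome, and these splits do not settle whether chance can be excluded for the interaction. With the MEF labels kept, 41 of 56 groupings of the GMP libraries gave at least 193 genes, with a median of 267 over the others, so a count of this size did not need the real GMP groups. These groupings all keep the MEF difference and do not settle it either.

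The fast-slow effect differed between GMP and MEF by the interaction test in 193 genes, a count that 41 of 56 groupings of the GMP libraries reached with the MEF labels kept. On the log2 scale, as the GMP effect minus the MEF effect, the named genes past the threshold were S1pr3 (7.64), Fn1 (7.62), Col12a1 (7.32), Thy1 (7.02), Nid1 (6.42), Igfbp4 (5.90), Col1a2 (4.80), Bgn (4.27), Tppp3 (-12.12), Crb3 (-12.00), L1td1 (-10.20), Ccnb1ip1 (-9.38), Srgn (-8.31), Nup210 (-8.20), Itga6 (-8.12), Stmn2 (-5.69), Sox2 (-5.62).

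Single libraries also lay far from the rest of their group. For normally distributed values chance would flag about 1 in 20 groups. CPM values are skewed, a group with counts in only 1 library is always flagged, and many genes were named for large folds. The share that chance gives here is thus not known, and the counts below cannot be read as an excess. Of 25 library measures and axis positions tested within a group, 4 had a library apart, and of 342 gene levels 53 did, some of them with counts in a single library of a group otherwise at 0. Rn45s and Lars2 took 48.86% of the counts of fast GMP replicate 2 (19.9% to 24.19% in the others). The median correlation with the own group was 0.94 for iPS replicate 1 (0.955 to 0.957 in the others), 0.67 for fast GMP replicate 1 (0.757 to 0.787) and 0.916 for fast MEF replicate 3 (0.963 to 0.97).

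In slow MEF replicate 3, Mcm5 was at 41.8 CPM (15.6 to 19.1 in the others), Bhlha15 was at 1.42 CPM (0.118 to 0.203 in the others) and Gng8 was at 132 CPM (8.32 to 19.9 in the others). In the same slow MEF library, Lce1h was at 0.274 CPM (0 in the others) and AU018091 was at 2.52 CPM (0.264 to 0.61 in the others). In slow MEF replicate 2, Foxd1 was at 1.22 CPM (0 in the others), Tlx2 was at 0.203 CPM (0 in the others) and Tnk1 was at 0.203 CPM (0 in the others). In the same slow MEF library, Miat was at 1.32 CPM (0 in the others), Siglecg was at 26.5 CPM (17.3 to 18.8 in the others) and Gpa33 was at 1.73 CPM (0.118 to 0.314 in the others). Slow MEF replicate 2 also stood apart where Zbtb32 was at 5.59 CPM (0 to 0.132 in the others), N4bp3 was at 1.02 CPM (0 to 0.157 in the others) and Mtap7 was at 1.73 CPM (0.236 to 0.314 in the others). Slow MEF replicate 2 also stood apart where Mcpt8 was at 16.1 CPM (4.72 to 5.42 in the others). In fast MEF replicate 3, Uhrf1 was at 843 CPM (462 to 516 in the others) and Sh3tc1 was at 3462 CPM (34.9 to 52 in the others). In the same fast MEF library, Bhlha15 was at 172 CPM (9.57 to 22.3 in the others), Siglecg was at 0.848 CPM (0 in the others) and Mtap7 was at 108 CPM (25.7 to 34.1 in the others). Fast MEF replicate 3 also stood apart where Csf2rb2 was at 32.9 CPM (0 to 0.0887 in the others). In fast MEF replicate 4, Dnajb5 was at 2.04 CPM (0 to 0.0966 in the others) and 6230427J02Rik was at 0.0855 CPM (0 in the others). In fast MEF replicate 1, Gzme was at 0.913 CPM (0 in the others), Kiss1r was at 120 CPM (42.9 to 47.2 in the others) and Dok2 was at 159 CPM (98.5 to 105 in the others). In bulk MEF replicate 3, Sox2 was at 4.84 CPM (0.119 to 0.869 in the others), Dppa4 was at 0.115 CPM (0 in the others) and Dnmt3b was at 1.84 CPM (0 to 0.217 in the others). In the same bulk MEF library, Klf4 was at 172 CPM (132 to 135 in the others), Usp18 was at 0.211 CPM (0 in the others) and Adh1 was at 0.105 CPM (0 in the others). Bulk MEF replicate 3 also stood apart where Xaf1 was at 4.98 CPM (0.251 to 0.524 in the others) and Dok2 was at 0.115 CPM (0 in the others). In iPS replicate 1, Mcm7 was at 975 CPM (1161 to 1191 in the others). In iPS replicate 3, Dok5 was at 0.159 CPM (0 in the others) and Gzme was at 0.106 CPM (0 in the others). In slow MEF replicate 1, Islr was at 106 CPM (28.2 to 34.8 in the others) and Ifi203 was at 57.5 CPM (9.11 to 14.4 in the others). In bulk MEF replicate 4, Islr was at 0.465 CPM (0 in the others), Nova2 was at 0.125 CPM (0 in the others) and Slc16a11 was at 72.2 CPM (2.12 to 6.64 in the others). In slow MEF replicate 4, A4galt was at 422 CPM (26.1 to 48 in the others) and Ltbp3 was at 412 CPM (111 to 140 in the others). In bulk MEF replicate 2, Nptx2 was at 99.8 CPM (45.9 to 49.4 in the others) and Dusp23 was at 128 CPM (1.91 to 4.15 in the others). In bulk MEF replicate 1, Perp was at 7.81 CPM (0.593 to 1.25 in the others). In fast MEF replicate 2, Fjx1 was at 0.84 CPM (0 in the others). In fast GMP replicate 4, Cdkn1a was at 3932 CPM (286 to 816 in the others). In fast GMP replicate 5, Klf4 was at 205 CPM (35.8 to 77.4 in the others). In fast GMP replicate 1, Meis1 was at 4.35 CPM (0 to 1.15 in the others). In iPS replicate 4, Crb3 was at 63.5 CPM (1.51 to 9.78 in the others) and Maf was at 1.16 CPM (0.212 to 0.335 in the others).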

How the results depend on the processing

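The fit without Rn45s and Lars2 was chosen after the data were seen, and all other alternatives before. The counts of genes not given here stayed within 1.5 times the reported count under every alternative run. With all 24 libraries in 1 fit, genes past the threshold were 385 for fast against slow GMP, 1246 for fast against slow MEF, 1069 for the interaction, 3170 for iPS against bulk MEF, 56 for slow against bulk MEF, 1513 for fast against bulk MEF, 692 for genes called the same way in MEF and iPS, and 12 for genes shared by the 3 fast against slow comparisons. With DESeq2 they were 97 for GMP, 1563 for the interaction, 1976 for slow against bulk MEF and 5 for the shared genes. The stricter filter gave 324 for the interaction. The fit of all 24 libraries takes 1 spread per gene over all groups. Fitted alone, the common biological coefficient of variation, a measure of spread between libraries, was 1.18 in fast against slow GMP. It was 0.59 to 0.63 in the comparisons among MEF and iPS. The counts of that fit for GMP thus lean on the spread of other groups, and those for MEF and iPS on the spread of GMP. How far this made the differences in counts was not tested, nor was a cause for the other alternatives. Leaving out 1 library gave 82 to 575 for the interaction and 759 to 998 for slow against bulk MEF, and 0 for GMP each time.

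Same-numbered libraries correlated at -0.054 to 0.077 in their deviations from the group means, so the numbers share no more than a label, and in none of the comparisons did every library correlate best with its own number. With the replicate block the interaction passed 92 genes. The axis difference of MEF was 0.365 with paired libraries (exact permutation p = 0.125, the smallest that 4 pairs allow) and 0.357 to 0.369 with 1 library left out. Without 1 fast or slow MEF library its exact p was 0.0571, the smallest that 4 against 3 allow, which says nothing about stability.

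Csf2rb2 in fast against slow MEF, at 1.94 and not past the threshold, turned to -3.92 with limma voom, to -2.98 with the replicate block, and ran from -5.51 (without fast MEF replicate 3) to 2.35 with 1 library left out. Of 1050 named pairs of gene and comparison, it was the only one to turn and pass the threshold in either fit, and 101 others changed sign under at least 1 alternative without passing in either. Those reported were Cdkn1a (-0.60 with limma voom, -0.93 with the block, -1.02 without fast GMP replicate 4), Mpo (-0.38 with the block), Myc (-0.02 without fast GMP replicate 3) and Klf4 (0.55 without slow GMP replicate 3), all in GMP. Of 208 reported pairs past the threshold, 31 were smaller and 84 larger by over 1.5 times, and 6 missed the threshold, without 1 library or another. Of all 1050 named pairs, DESeq2 kept the side of the threshold of 931, brought 105 past it and lost 14. The fit of all 24 libraries kept 833, brought 52 and lost 165, and leaving out Rn45s and Lars2 kept 1040. An estimated correlation ended 39 list calls and kept the outcome of 135, and the replicate block brought 2 lists past the threshold and kept 172. For named pairs the block kept 1009, brought 11 and lost 30. The median of all genes shifted by 0.152 for the interaction with DESeq2 size factors and by 0.121 for fast against bulk MEF with upper-quartile factors. Thinning to the smallest library moved 2 named pairs below the threshold and 9 past it, with 0 of them in fast against slow GMP.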

Other observations

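The keratinocyte list was chosen after its values were seen, and the other lists before. In fast against slow MEF, 1 of 4 neutrophil maturation genes rose, 2 of 12 early progenitor genes rose and 4 fell, 1 of 3 erythroid and megakaryocyte genes fell, 1 of 4 pan-hematopoietic genes rose and 1 fell, 2 of 3 endothelial genes rose, 1 of 3 genes of differentiating pluripotent cells rose and 1 fell, and 3 of 6 nuclear retained RNAs fell (camera adjusted p = 0.817, 0.524, 0.507, 0.483, 0.344, 0.725 and 0.109). Primary granule, monocyte, lymphoid, skeletal muscle and sex linked genes had 2, 2, 1, 1 and 2 tested members there and no list test. In fast against slow GMP, the monocyte, pan-hematopoietic and skeletal muscle lists had 17, 14 and 3 tested genes and none passed (camera adjusted p = 0.658, 0.909 and 0.598). The list of mitochondrially encoded genes had 0 members among the gene symbols.

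The camera p-values of the keratinocyte list were not adjusted over lists. Of 18 keratinocyte genes, 15 rose and 0 fell in fast against slow MEF (15 adjusted over the list alone, camera unadjusted p = 4.98e-10, and unadjusted p = 0.00434 with an estimated correlation). In slow against bulk MEF 6 of 12 keratinocyte genes rose and 1 fell (camera unadjusted p = 0.0184, and unadjusted p = 0.101 with an estimated correlation). The Yamanaka list, with 3 of 4 genes higher in iPS than in bulk MEF, did not pass there (camera adjusted p = 0.084).

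For some lists the median, the mean and the test had different signs. In fast against slow MEF this held for glycolysis (median -0.1, mean 0.09, test upward) and neutrophil maturation (-1.01, -0.16, upward). In slow against bulk MEF it held for inhibitors (-0.1, 0.24, upward), p53 targets (-0.06, 0.14, downward) and neutrophil maturation (0.65, -0.42, downward). In iPS against bulk MEF it held for nuclear retained RNA (-0.53, 1.0, upward) and neural genes (-0.71, 1.5, upward), and in fast against bulk MEF for endothelial (-0.85, 0.96, upward) and differentiation genes (-2.48, 0.04, downward). In GMP it held for S phase (0.11, 0.14, downward), G2 and mitosis (0.01, -0.15, downward), inhibitors (0.29, -0.02, upward), p53 targets (-0.04, 0.02, downward), extracellular matrix (-0.2, 0.2, downward), nucleolar (0.01, 0.2, downward), cholesterol (0.13, -0.01, upward), imprinted (-0.08, 2.03, upward) and nuclear retained genes (-0.99, 0.52, downward). In the interaction it held for primary granule (0.22, -0.77, downward), early progenitor (-1.03, 0.2, downward) and differentiation genes (0.35, 0.28, downward).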
